A study of Mus musculus with 6 samples.

How the data were processed

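Small RNA was profiled by sequencing in C2C12 cells, a mouse myoblast line that can be grown as dividing cells or made to fuse into muscle fibres. There were 6 libraries, 3 from control cells and 3 from cells given TGF-beta, and the group of each was taken from its treatment label. The labels give no dose, duration or TGF-beta isoform. The titles of the treated libraries end in b and a number, which was read as a replicate number because the descriptions number the replicates. The labels' extraction text speaks of retinas and of a general RNA library kit, which does not match the cell line named in the other labels, so miRNAs known from the retina were examined as a separate list. The labels do not say that the libraries came from separate cultures, so p-values measure the spread between these libraries, which may be partly technical.

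The authors deposited 1 table with 1065 miRNA names, of which 1028 are known mouse miRNAs and 37 are predicted miRNAs with a running number. The genome build was mm9, per the submitters' processing notes. The aligner, the counting tool, the miRNA annotation and the treatment of reads that match several miRNAs are not given in the sources used here. The authors' values are headed TPM, but in each library they sum to 1000000 and are whole multiples of a single step, so they are RPM, the reads of a name per 1000000 miRNA reads of the library, with no correction for length. The deposited table also holds the authors' group means in RPM and an unadjusted p-value for each name. Recomputed from the deposited RPM values, those p-values were those of a two-sided equal-variance two-sample test on the unlogged values.

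The step of each library gave back the read counts. All values (100%) were whole reads to within 0.01 read. The libraries held 9015669 to 9813063 miRNA reads, so that 1 read was worth 0.102 to 0.111 RPM and a value of 0 allows up to 3 reads, or 0.306 to 0.333 RPM. Such floors cover counting error only, because it is not known here whether PCR copies were marked by molecular identifiers. Pairs of replicates were compared by a chi-square test of their reads over miRNAs. All pairs differed far more than by sampling noise, with a chi-square per degree of freedom of 90.0 to 393, so no library was treated as a copy of another. This does not tell whether the libraries came from separate cultures.

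The main comparison used limma 3.58.1 in R 4.3.3 with an intensity trend on log2(RPM + 1), as laid down for normalized values before the data were examined. Names with at least 1 RPM in at least 3 libraries were tested. This kept 418 names and left out 647, which held at most 0.0131% of the reads of any library. A two-sided Benjamini-Hochberg adjusted p under 0.05 was the threshold. Fold changes are on the log2(RPM + 1) scale, which understates the change of low miRNAs. The miRNAs named in the text are the 12 with the largest positive and the 12 with the largest negative log2 fold change among those past the threshold, with groups that did not overlap and a mean of at least 10 RPM. The 10 most abundant miRNAs and up to 4 abundant members of each list are named as well. Further miRNAs that are named were chosen after their values were seen. This rule, the tests, the 23 lists and most alternatives were written before the data were examined.

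Lists with at least 3 tested members were tested with camera from limma, with a preset correlation of 0.01, and with Benjamini-Hochberg adjustment over 18 lists. Camera with an estimated correlation and fry were run beside it. The ratio of the 5p to the 3p arm of a hairpin was tested with limma on log2((5p + 1)/(3p + 1)) for hairpins with a mean of at least 10 RPM in both arms. The share of reads taken by the most abundant miRNAs was compared by a two-sided exact permutation test, whose smallest p for 3 against 3 libraries is 0.1.

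On simulated data made from the real means, with 1065 names of which 200 were changed, the comparison of TGF-beta with control was run 20 times. The limma step recovered 45.5% of the tested names changed by 1.5 times and 78.5% of those changed by 2 times, and 7.90% of its calls were false. In these runs the most abundant miRNA was never changed, and rises and falls were equal in number. The rates therefore do not cover a shift of all other shares by a rise of that miRNA. With nothing changed it made 0.1 calls per run. The arm step recovered 88.9% of hairpins in which 1 arm was changed by 2 times.

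The alternatives were other pseudocounts, filters and scalings, each library left out in turn and the replicate number as a block. After the data were seen, count tests on the recovered reads were added with edgeR 4.0.16, limma-voom and DESeq2 1.42.0, since a count test is no main test for RPM values. Values rescaled without miR-21a-5p, and a single name kept from each set of names that share reads, were added at the same stage. Hairpin genes, their host genes and their neighbours were looked up by name in GENCODE M21, which is on GRCm38. Of the 1028 known names, 962 matched at least 1 hairpin gene. No coordinates are given, because that build is not the build of the deposited table. Mature sequences were not used here.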

Results

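Mature miRNAs were counted in 6 small RNA libraries of C2C12 myoblasts, 3 from control cells and 3 from cells treated with TGF-beta, a cytokine known to hold back muscle differentiation and to drive fibrosis. The series asks which miRNAs of myoblasts respond to TGF-beta, in the setting of fibrosis of skeletal muscle. Depth was even, with 9273231 to 9813063 miRNA reads in the 3 control and 9015669 to 9450936 in the 3 TGF-beta libraries. TGF-beta replicate 3 stood somewhat apart from its group, with a mean correlation of log values across miRNAs of 0.994 to the other treated libraries, against 0.995 to 0.997 for the other libraries within their groups.

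The libraries were dominated by few miRNAs. miR-21a-5p, a miRNA often raised in fibrotic tissue, was the most abundant and took 27.03% ± 1.12 of the miRNA reads in control and 35.2% ± 1.41 in TGF-beta libraries (SD, n = 3 each). miR-206-3p, a miRNA of skeletal muscle, was next in control with 12.7% ± 0.88 and took 8.64% ± 0.20 in TGF-beta libraries, where the mean of miR-27b-3p was higher at 9.06% ± 1.69. Control and treated values of miR-21a-5p and of miR-206-3p did not overlap. The 10 most abundant miRNAs together took 72.6% ± 0.31 of the reads in control and 74.6% ± 0.96 in TGF-beta libraries, and all 3 treated values lay above all 3 control values. A two-sided exact permutation test gave p = 0.1 for the share of the most abundant miRNA and for that of the top 10, the smallest value that 3 against 3 libraries allow. The share of the 20 most abundant miRNAs differed by 0.287 percentage points, with an exact permutation p of 0.3. Of the other abundant miRNAs, miR-27b-3p, let-7i-5p, let-7f-5p, let-7c-5p, miR-143-3p, let-7g-5p and miR-99b-5p did not pass the test described next, with log2 fold changes between −0.11 and 0.01.

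**Figure D1:**
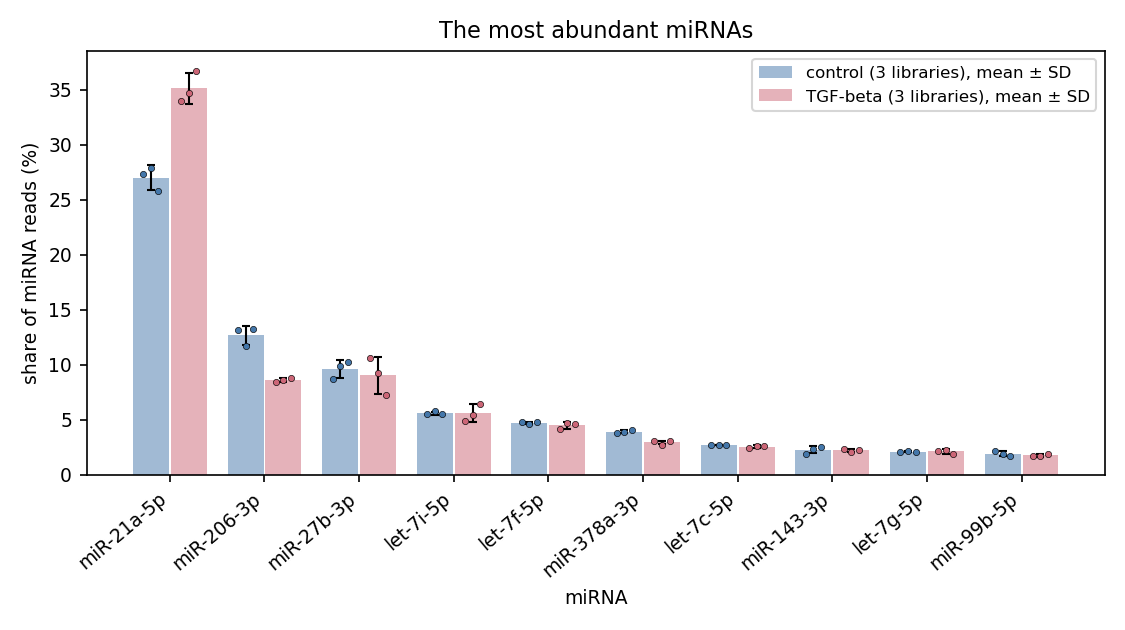
Share of all miRNA reads (%) of the 10 most abundant miRNAs, with bars for the mean of 3 control (blue) and 3 TGF-beta (red) libraries, error bars for the SD and points for single libraries. miR-21a-5p moved from 27.03% to 35.2% and miR-206-3p from 12.7% to 8.64%.

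Which miRNAs differed between treated and control cells was tested with limma over 418 names. The rises with the smallest adjusted p were those of miR-155-5p, miR-199a-5p and miR-92a-3p. miR-155-5p, an inflammation-linked miRNA made from the noncoding host gene Mir155hg, rose from 214.4 ± 5.59 to 387 ± 34.6 RPM (SD, n = 3 each), with a log2 fold change of 0.84 (SE 0.13, limma with Benjamini-Hochberg, adjusted p = 0.000479). miR-199a-5p, a pro-fibrotic miRNA with a hairpin in the noncoding gene Dnm3os, rose from 3106 ± 36.8 to 4951 ± 156 RPM, with a log2 fold change of 0.67 (SE 0.10). miR-92a-3p, a member of the growth-promoting miR-17 to 92 cluster, rose from 774 ± 101 to 1365 ± 72.0 RPM, with a log2 fold change of 0.82 (SE 0.13). miR-21a-5p, whose hairpin lies in an exon of Vmp1, rose by 0.38 on the log2 scale (SE 0.07, limma adjusted p = 0.00146), a call that ended without a filter on low values, at the same fold (SE 0.11, limma adjusted p = 0.110). The largest rise among names with a mean of at least 10 RPM was that of the predicted name novel_79, at 0.90 (SE 0.18), from 13.3 ± 1.05 to 26.1 ± 6.92 RPM, a call that ended with quantile normalization (0.88, limma adjusted p = 0.108), as did that of miR-582-3p (0.85, limma adjusted p = 0.0615). miR-181a-2-3p rose by 0.87 (SE 0.15), miR-582-3p, from an intron of Pde4d, by 0.82 (SE 0.16), and miR-27a-5p by 0.79 (SE 0.14), from 476 ± 37.9 to 825 ± 107 RPM. Smaller rises were found for miR-16-1-3p (0.61), miR-17-5p (0.60), miR-7a-5p (0.54), miR-27b-5p (0.53) and miR-125b-1-3p (0.46). These calls were less firm and ended in 4, 8, 6, 7 and 8 of 25 alternatives. Those of miR-17-5p (limma adjusted p from 0.0557 to 0.242) and miR-125b-1-3p (from 0.0512 to 0.159) were lost when any library other than TGF-beta replicate 3 was left out. The call of miR-16-1-3p was lost without control replicate 1, control replicate 3 or TGF-beta replicate 2 (limma adjusted p from 0.0505 to 0.110), and that of miR-7a-5p without control replicate 3, TGF-beta replicate 2 or TGF-beta replicate 3 (from 0.120 to 0.180). That of miR-27b-5p was lost without control replicate 1, control replicate 3, TGF-beta replicate 1 or TGF-beta replicate 2 (limma adjusted p from 0.1003 to 0.278).

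Muscle miRNAs were among those that fell. miR-206-3p, which promotes myoblast differentiation, fell from 126884 ± 8764 to 86350 ± 1986 RPM (SD, n = 3 each), with a log2 fold change of −0.55 (SE 0.08, limma with Benjamini-Hochberg, adjusted p = 0.000479). Its call ended with quantile normalization (−0.21, limma adjusted p = 0.277). miR-486a-5p, a muscle-enriched miRNA from an intron of Ank1, fell from 757 ± 65.7 to 439 ± 32.3 RPM, with a log2 fold change of −0.78 (SE 0.13, limma adjusted p = 0.000538). miR-486a-3p and miR-486b-3p gave almost the same reads in every library and stand for the same signal. miR-1a-3p, another muscle miRNA, fell from 19024 ± 2539 to 14164 ± 2008 RPM, with a log2 fold change of −0.43 (SE 0.12, limma adjusted p = 0.0363), and miR-1b-5p, annotated on the opposite strand of the same place, had almost the same reads. The largest fall among miRNAs with a mean of at least 10 RPM was that of miR-188-5p, from 36.5 ± 5.23 to 19.6 ± 2.42 RPM, with a log2 fold change of −0.86 (SE 0.16, limma adjusted p = 0.00171), and its call ended with quantile normalization (−0.84, limma adjusted p = 0.0612). miR-532-5p, from the same hairpin cluster in an intron of Clcn5, fell by 0.44 (SE 0.10). miR-378a-3p, from an intron of the metabolic regulator Ppargc1b, fell from 39307 ± 1198 to 29463 ± 1708 RPM, with a log2 fold change of −0.42 (SE 0.09). Falls were also found for miR-503-5p (−0.70), miR-218-5p (−0.67) and miR-6540-5p (−0.56). Without TGF-beta replicate 2 the calls of miR-503-5p and miR-218-5p were lost (limma adjusted p = 0.0798 for both), and that of miR-532-5p was lost without it or without control replicate 1 (from 0.0557 to 0.0776). Those of miR-1a-3p and miR-1b-5p were lost without control replicate 1, control replicate 3, TGF-beta replicate 2 or TGF-beta replicate 3 (limma adjusted p from 0.106 to 0.220), and that of miR-6540-5p when any library other than control replicate 3 was left out (from 0.0712 to 0.227).

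**Figure D2:**
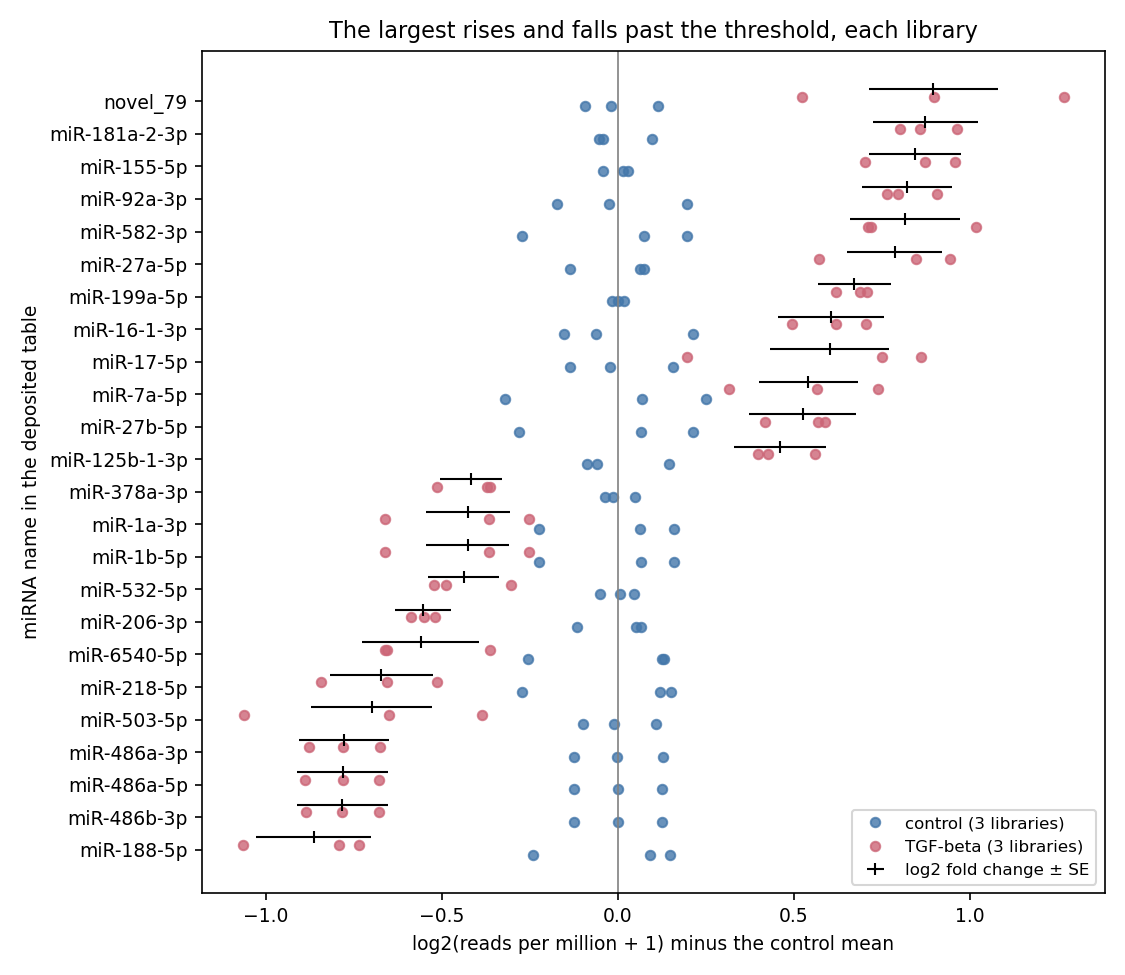
Log2(RPM + 1) of each library minus the control mean, for the 12 largest rises and 12 largest falls; blue points are 3 control and red points 3 TGF-beta libraries, and the black mark is the log2 fold change with its SE. Treated and control values of these names did not overlap; the fold changes ran from −0.86 for miR-188-5p to 0.90 for novel_79.

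In all, 33 of 418 names passed the threshold of limma with Benjamini-Hochberg adjustment, 17 higher and 16 lower with TGF-beta. Of these, 32 had groups that did not overlap, against 89 of all 418 tested, where chance gives 10%. The exception was miR-20a-5p, which rose by 0.62 (SE 0.19) with 1 treated library inside the control range. At 26 of the 33 names the mean was at least 10 RPM, and the changes were modest, from 0.38 to 1.16 in absolute log2 terms. The largest, for miR-335-3p at −1.16, rests on means of 3.67 and 1.08 RPM. A quasi-likelihood test of edgeR on the recovered reads called 29 names, 19 higher and 10 lower, and median scaling gave 20 higher and 10 lower. With miR-21a-5p left out and the rest rescaled, the median log2 fold change of all names moved up by 0.16, the split became 25 higher and 7 lower, and among the falls named above the calls of miR-1a-3p, miR-1b-5p, miR-378a-3p, miR-532-5p, miR-503-5p and miR-6540-5p ended. The count was 18 without control replicate 1, 17 without TGF-beta replicate 2 and 36 without TGF-beta replicate 3. Quantile normalization ended 17 of the 25 calls named by the fixed rule. The calls of miR-6540-5p, miR-1b-5p and miR-1a-3p were the least firm of these and were lost in 19 of 25, 16 of 24 and 16 of 25 alternatives.

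Groups of miRNAs were then compared, using lists fixed before any value was seen. Of 18 lists with enough tested members, 6 passed the threshold of camera with the preset correlation. The muscle-enriched list was lower with TGF-beta. Of its 6 tested members, 3 fell (miR-206-3p, miR-1a-3p and miR-486a-5p) and none rose, over all names as well as adjusted over the list alone, and the median log2 fold change was −0.42 (camera adjusted p = 0.000197, and adjusted p = 0.353 with an estimated correlation). The median was −0.25 without TGF-beta replicate 3 and −0.25 with miR-21a-5p left out. miR-133a-3p had a log2 fold change of −0.30 (SE 0.18) and miR-133b-3p of −0.41 (SE 0.18), and neither passed. In the miR-199 and miR-214 group, higher with TGF-beta, 1 of 5 tested members rose, miR-199a-5p, with the same count adjusted over the list alone, and all 5 values were positive with a median of 0.27 (camera adjusted p = 0.00248, and adjusted p = 0.353 with an estimated correlation). miR-199a-3p had a log2 fold change of 0.32 (SE 0.13) and miR-214-3p of 0.21 (SE 0.15). miR-199a-3p passed at 0.49 without TGF-beta replicate 3, the library that stood apart (limma adjusted p = 0.0136), and at 0.49 with miR-21a-5p left out (limma adjusted p = 0.0168). Among the miR-17 to 92 clusters and their paralogs, 3 of 14 tested members rose (miR-92a-3p, miR-17-5p and miR-20a-5p), and 4 when adjusted over the list alone, with miR-25-5p added. The list median was 0.17 (camera adjusted p = 0.00248, and adjusted p = 0.353 with an estimated correlation), and the abundant member miR-25-3p was at 0.04 (SE 0.11).

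Of the miRNAs described as promoted by TGF-beta or pro-fibrotic, 3 of 17 tested members rose, namely miR-21a-5p, miR-199a-5p and miR-155-5p, with the same count adjusted over the list alone. The list median was 0.08 (camera adjusted p = 0.00779, and adjusted p = 0.359 with an estimated correlation). Of the inflammation list, 2 of 7 rose, miR-155-5p and miR-21a-5p, both also in the pro-fibrotic list, with the same count adjusted over the list alone and a median of 0.06 (camera adjusted p = 0.0193, and adjusted p = 0.353 with an estimated correlation). miR-146b-5p had a log2 fold change of 0.06 (SE 0.11). Of the anti-fibrotic list, 2 of 17 fell, miR-206-3p and miR-486a-5p, both also muscle-enriched, and 3 fell when adjusted over the list alone, with miR-30c-5p added. The list median was −0.17 (camera adjusted p = 0.0193, and adjusted p = 0.353 with an estimated correlation). Without TGF-beta replicate 3, 4 lists passed; the inflammation list had an adjusted p of 0.119 and the anti-fibrotic list of 0.278. Without control replicate 1 the inflammation list had an adjusted p of 0.0733, and without TGF-beta replicate 2 the anti-fibrotic list had 0.0507. With miR-21a-5p left out, these lists had adjusted p values of 0.139 and 0.0654, and the median of the anti-fibrotic list went from −0.17 to −0.01. The other medians moved up as well, to 0.23 for the pro-fibrotic list, 0.19 for the inflammation list, 0.33 for the miR-17 to 92 list and 0.44 for the miR-199 and miR-214 group. miR-21a-5p is itself a member of the inflammation and pro-fibrotic lists, which therefore also lost a member in this setting. The anti-fibrotic list was only rescaled. With quantile normalization the pro-fibrotic median was 0.05 and the inflammation median 0, and without control replicate 3 the miR-17 to 92 median was 0.06. With single libraries left out the inflammation median ran from 0.0034 without TGF-beta replicate 3 to 0.12 without control replicate 2.

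**Figure D3:**
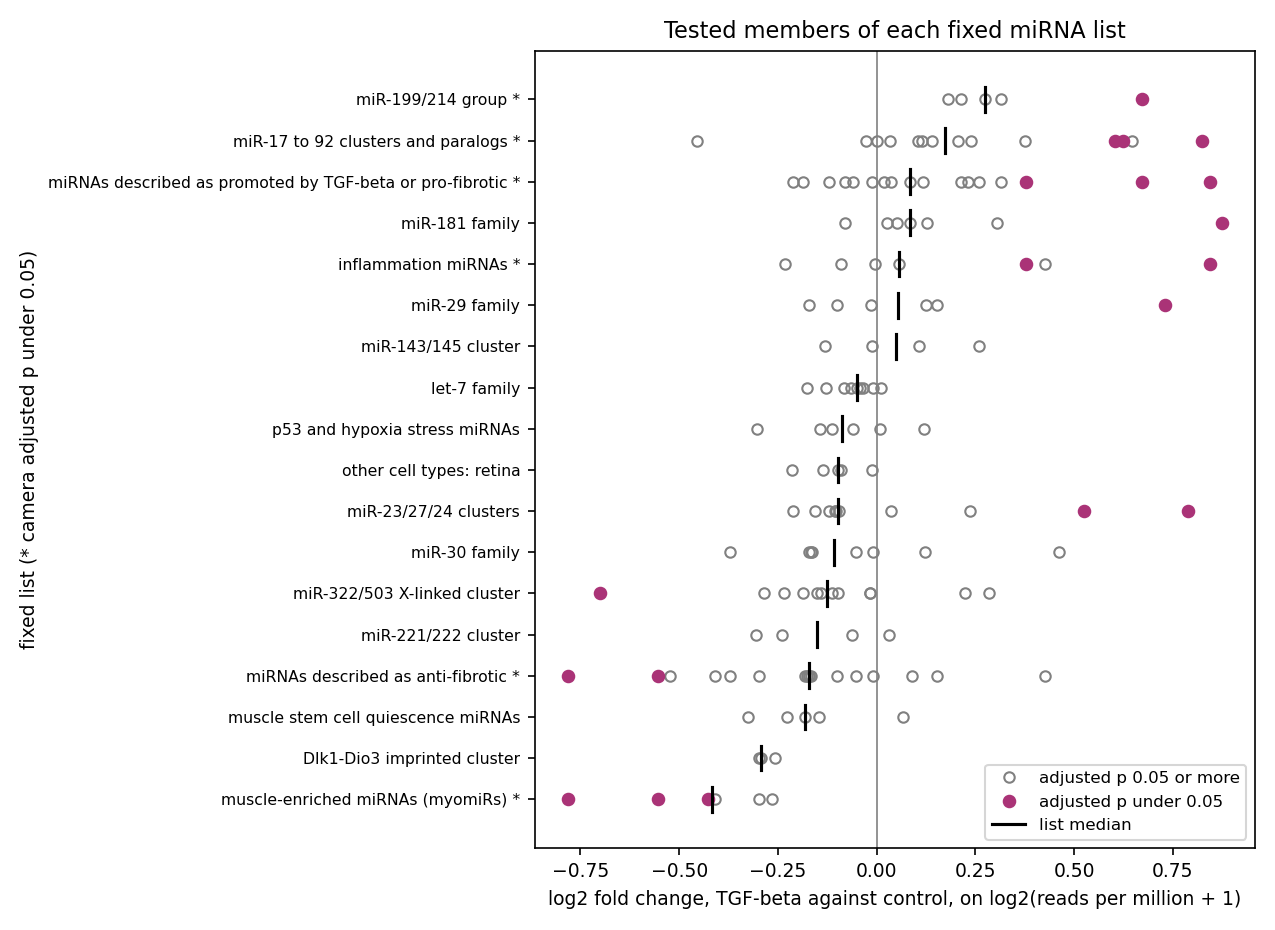
Log2 fold change (TGF-beta against control, on log2(RPM + 1)) of each tested member of 18 fixed lists; filled points passed the threshold, open points did not, and the bar is the list median. The medians ran from −0.42 for muscle-enriched miRNAs to 0.27 for the miR-199 and miR-214 group, and a star marks the 6 lists that passed camera.

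Other lists, which did not pass, held 1 or 2 members past the threshold. In the clusters of miR-23, miR-27 and miR-24 2 of 10 tested members rose, miR-27a-5p and miR-27b-5p, while miR-27a-3p had a log2 fold change of −0.12 (SE 0.13), and the list's median (−0.10) and its mean (0.08) differed in sign (camera adjusted p = 0.447). In the miR-181 family 1 of 7 rose, miR-181a-2-3p, while miR-181a-5p was at 0.08 (SE 0.13; camera adjusted p = 0.0748 for the list). This list passed with miR-21a-5p left out (camera adjusted p = 0.0421), though not with an estimated correlation in the main scaling (adjusted p = 0.353). In the miR-29 family 1 of 6 rose, miR-29b-1-5p at 5.33 ± 0.71 RPM with TGF-beta, while the antifibrotic miR-29a-3p was at 0.15 (SE 0.13; camera adjusted p = 0.447) and passed at 0.32 without TGF-beta replicate 3 (limma adjusted p = 0.0278). In the cluster of miR-322 and miR-503 1 of 12 fell, miR-503-5p, and miR-351-5p was at −0.28 (SE 0.13; camera adjusted p = 0.447). Counts adjusted over these lists alone were the same. Of the 2 arms of the miR-21 hairpin, too few for a list test, miR-21a-5p rose and miR-21a-3p was at 0.23 (SE 0.19).

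In the remaining lists no member passed over all names. Of the miR-30 family 0 of 8 passed, with miR-30c-5p nearest at −0.37 (SE 0.12, limma adjusted p = 0.0592); over the list alone miR-30d-3p passed as higher and miR-30c-5p as lower (camera adjusted p = 0.614). None of the 9 let-7 members (camera adjusted p = 0.517), 4 of the cluster of miR-143 and miR-145 (0.517), 4 of the cluster of miR-221 and miR-222 (0.447), 5 quiescence miRNAs of muscle stem cells (0.466), 6 miRNAs of p53 and hypoxia stress (0.790) or 3 of the Dlk1-Dio3 cluster (0.447) passed, over all names or over the list alone. Without TGF-beta replicate 3, miR-145a-5p went from 0.26 to 0.44 and passed (limma adjusted p = 0.0165), and without TGF-beta replicate 1 miR-30c-5p passed at −0.42 (limma adjusted p = 0.0477). miR-143-3p was at −0.01 (SE 0.11), miR-222-3p at −0.31 (SE 0.13), miR-31-5p at −0.15 (SE 0.15) and miR-34c-5p at 0.12 (SE 0.13). No direction is given for the let-7, miR-30, miR-23 with miR-27 and miR-24, miR-322 with miR-503, miR-221 with miR-222, p53 and hypoxia, and retina lists, because the sign of their median turned when miR-21a-5p was left out.

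Markers of other cell types did not pass. Of 8 retina miRNAs, 7 were listed and 5 tested, and none passed (camera adjusted p = 0.495). These tests compare treated with control libraries, so they cannot tell whether another tissue was present in both groups. The levels were not compared with those of any retina sample. Of this list, miR-124-3p was not listed, and miR-204-5p and miR-211-5p were listed but below the tested level. The most abundant tested members were miR-182-5p, miR-183-5p and miR-9-5p. miR-9-5p stood at 1408 ± 16.4 RPM in control and 1215 ± 94.9 RPM in TGF-beta libraries (SD, n = 3 each), and miR-182-5p and miR-183-5p at 3974 ± 391 and 2770 ± 122 RPM in control. Markers of blood, endothelium and liver and the epithelial miR-200 family had 1 tested member each, none of which passed. In control these were miR-142a-3p at 1.05 ± 0.50, miR-126a-3p at 16.7 ± 6.56, miR-122-5p at 1.30 ± 0.39 and miR-200c-3p at 1.45 ± 0.47 RPM.

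Whether the arms of a hairpin moved apart was tested for 52 hairpins. The miR-27a hairpin had the largest difference, with a log2 5p to 3p ratio of −2.88 ± 0.33 in control and −1.97 ± 0.30 in TGF-beta libraries (SD, n = 3 each), higher in all 3 treated libraries. The ratio of miR-27b was also higher, by 0.63 (SE 0.14), and that of miR-30d was lower, at −0.63 (SE 0.15), each in all 3 treated libraries. None passed limma with Benjamini-Hochberg adjustment, where the smallest adjusted p was 0.116 and 0 of 52 hairpins were called. At an unadjusted p under 0.05 there were 6, and 7 hairpins had groups that did not overlap, where chance gives 10%.

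The authors' deposited table gave an unadjusted p under 0.05 for 80 of 1065 names, of which 3 stayed under 0.05 after Benjamini-Hochberg adjustment. Of the 33 names called by limma, 28 had a p under 0.05 in the authors' deposited table, and 21 of its 80 were below the level tested here.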

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

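The search among names below the tested level was set up after the main results were seen, and a stricter form of it, which also asked for a limma call, had found none. miR-181b-2-3p was picked there because a quasi-likelihood test of edgeR without a filter called it higher with TGF-beta. It had 27 reads over the 3 TGF-beta libraries and 4 over the 3 control libraries, which is a mean of 0.970 RPM against 0.137 RPM. The edgeR test that picked it gave a log2 fold change of 2.72 (Benjamini-Hochberg adjusted p = 0.0268), which is the ground of the choice and no further support. Its hairpin neighbours that of miR-181a-2-3p, which rose by 0.87 in the main comparison.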

How the results depend on the processing

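The count tests, the scalings without miR-21a-5p and the removal of names that share reads were chosen after the data were seen. Of 33 miRNAs called, the count was 19 with no filter, 19 with a mean of at least 10 RPM and 10 with quantile normalization. The cause was not tested. Quantile normalization sets values by rank, so those of miR-21a-5p and miR-378a-3p (rank 1 and 6 in every library) are fixed and test nothing. miR-206-3p could take only the values of rank 2 or 3. It went to −0.21 (SE 0.08, limma adjusted p = 0.277), and its call ended. Of 25 named calls, 17 ended with quantile normalization, 8 with no filter and 6 with a mean of at least 10 RPM. With single libraries left out it ran from 17 to 36. It was 26 with DESeq2, 30 with voom, 32 without miR-21a-5p, 28 (22 higher, 6 lower) when the filter was then applied again, and 30 with 1 name kept per set. Of the 6 lists called, 0 passed with an estimated correlation (1 at an unadjusted p under 0.05), 0 with fry for a shared direction (10 with fry for either direction) and 3 with quantile normalization, where the pro-fibrotic, inflammation and anti-fibrotic lists were lost, for causes not tested, and 4 to 6 with single libraries left out. The difference of 2.02 percentage points in the share of the top 10 became 8.13 for the top 1, 3.31 for the top 5 and 0.287 for the top 20, as fewer or more miRNAs are summed, and 1.48 to 2.42 with single libraries left out. The count of hairpins was 0 in all 9 alternatives run. No named miRNA or list past the threshold turned its direction. The replicate numbers did not pair the libraries, with correlations of deviations of −0.17, −0.20 and −0.08 for equal numbers and no library closest to its own number. With the number as a block the counts were 32 miRNAs, 6 lists and 0 hairpins, and of the named calls that of miR-125b-1-3p ended (limma adjusted p = 0.0669). The top 10 difference was then 2.02 points (exact permutation p = 0.25, the smallest that 3 such blocks allow). The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. As many miRNAs as in the real split (33, highest other 0) came from 1 split, the real one, as many lists (6, highest other 2) from 1 split, and as many hairpins (0, highest other 0) from 10. Depth limits the names below about 1 RPM, where a library holds about 10 reads.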

Other observations

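The tests in this part were chosen after the results were seen, except the arm ratios and some on the muscle-enriched list. Those were the ones with a library left out, with an estimated correlation and with fry. For the other arms of the miR-188 cluster the prediction was written before its test. The cluster itself was picked after the falls of its miRNAs were seen. Arms were paired by name. Of the 17 names that rose, 8 were the less abundant and 5 the more abundant of their pair, and 4 had no partner by name. Of the 16 that fell, 3 were the less abundant and 10 the more abundant, and 3 had no partner. With names that share reads removed, the falls were 2, 8 and 1. A partner name such as miR-29b-3p can hold reads of several hairpins, so the pairs are not always the arms of a single hairpin. No test of these counts was made. The same shares over all tested names are not given, so the counts alone do not show a pattern of arms. The more abundant arms that rose were miR-21a-5p, miR-155-5p, miR-582-3p, miR-17-5p and miR-20a-5p. Among the less abundant, miR-27a-5p rose by 0.79 (SE 0.14) at 476 RPM in control, while its partner miR-27a-3p, at 3533 RPM, was at −0.12 (SE 0.13). miR-148a-5p rose by 0.86 (SE 0.19) from 6.02 to 11.6 RPM, while miR-148a-3p, at 4911 RPM in control, was at −0.02 (SE 0.15). miR-199a-5p, less abundant as well, rose with a partner, miR-199a-3p, that was at 0.32 (SE 0.13). miR-27b-5p rose and miR-27b-3p was at −0.10 (SE 0.11), and miR-29b-1-5p rose and miR-29b-3p was at −0.10. The ratio of the arms was tested for miR-27a and miR-27b, which did not pass (limma adjusted p = 0.116 for both), and not for miR-148a and miR-29b.

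Hairpins that lie close together were compared as 22 clusters. The cluster of miR-206 and miR-133b, in the noncoding gene Gm28653, was lower with TGF-beta, with a median log2 fold change of −0.49 over 4 arms, of which miR-206-3p fell (camera adjusted p = 0.00492, and adjusted p = 0.505 with an estimated correlation). miR-133b-5p was at −0.47 (SE 0.18) and miR-206-5p at −0.51 (SE 0.20), and neither passed. The cluster in the Clcn5 intron, with miR-188, miR-532, miR-362, miR-500 and miR-501, was lower as well, with a median of −0.34 over 9 arms, of which 2 fell (camera adjusted p = 0.00492, and adjusted p = 0.558 with an estimated correlation). No other cluster passed. That of miR-17, miR-19a and miR-20a, without miR-92a-3p among its tested arms, had a median of 0.29 over 4 arms (camera adjusted p = 0.431). That of miR-106b, miR-93 and miR-25 had a median of 0.11 over 6 arms (camera adjusted p = 0.391).

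Both miR-188-5p and miR-532-5p fell. The 7 other tested arms of their cluster had a median log2 fold change of −0.30, with 6 negative (camera p = 0.0251, and p = 0.313 with an estimated correlation), which is consistent with a lower level of the whole cluster, as a hypothesis. A rise of miR-21a-5p within a fixed total, which lowers every other share, is argued against for miR-188-5p, which was still at −0.71 (SE 0.17, limma adjusted p = 0.00782) with miR-21a-5p left out. For miR-532-5p this cannot be told apart, since its log2 fold change went from −0.44 (SE 0.10) to −0.27 (SE 0.11) and its call ended (limma adjusted p = 0.140) because the fold shrank. The median of the 7 other arms went to −0.13 with miR-21a-5p left out, against 0.11 for all names, and an effect of TGF-beta on the host transcript stays open, as untested.

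The lower level of the muscle-enriched list might also follow from the share taken by miR-21a-5p or from the library that stood apart. With miR-21a-5p left out the list median went from −0.42 to −0.25, and that of all names from −0.05 to 0.11. The mean log2 value of the 6 members then differed by −0.29 (SE 0.13) with groups that overlapped (exact permutation p = 0.2). For the level of the list as a whole, the rise of miR-21a-5p therefore cannot be told apart. Relative to the other names the list stayed lower in that setting (camera adjusted p = 0.000276 with the preset correlation). Camera compares the list with the other names, so a shift shared by all of them hardly changes it. The rise of miR-21a-5p is argued against for miR-206-3p, then at −0.38 (SE 0.08), and miR-486a-5p, at −0.61 (SE 0.13), both past the threshold. miR-1a-3p went from −0.43 (SE 0.12) to −0.26 (SE 0.11) and its call ended as the fold shrank. Without TGF-beta replicate 3 the list median was −0.25 with an adjusted p of 0.0104, which argues against that library alone. A response of the muscle miRNAs to TGF-beta stays open as a hypothesis, and over the alternatives the adjusted p of the list ran from 2.48e-06 without control replicate 2 to 0.353 with an estimated correlation, with 0.0780 by fry.

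Some names had nearly equal reads in every library, with 15 pairs within a ratio of 1.1 among names with a mean of at least 100 reads. In 10 of these pairs the ratio varied less than counting noise, which independent molecules would not give, and which is consistent with the same reads being counted under each of several overlapping names. Of the 10 pairs, 5 are annotated in GENCODE M21 on opposite strands of the same place, among them miR-24-3p with miR-3074-5p and miR-1a-3p with miR-1b-5p. miR-467a-5p and miR-467b-5p had 4766 reads each over the 6 libraries. Such names are uncertain as separate miRNAs, and with 1 name kept from each of the 8 sets 30 calls were made.

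The smallest p in the authors' deposited table, 2.29e-07, belongs to miR-466f-5p, which had 0 reads in each control library and 1 read in each TGF-beta library. There, novel_198 had 6 reads in each control and 9 in each TGF-beta library, with a p of 4.09e-05.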
